A study of Mus musculus with 9 samples.

How the data were processed

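RNA from RAW264.7 mouse macrophages was sequenced by the submitters in 9 samples, 3 each of CON, LPS and ProNa, grouped here by sample title. The extraction text in the labels speaks of colonic segments, although every sample is labelled as the cell line. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used with the mouse build GRCm39, and no versions are given in the sources used here. StringTie assembles transcripts from aligned reads, so the matrix holds 140725 reference transcripts and 12638 assembled ones, 153363 in all.

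Of the 3 files, 2 were used and an annotation text was not used here. The first holds FPKM per transcript, the unit given per the file headers. Its 3 columns named CON, LPS and ProNa were used as the authors' group means. A further 9 columns hold values per library under names that no label gives, so they could not be assigned to samples and were not used in any step. The second is the authors' deposited table of 53700 genes with a log2 fold change, a p-value and an adjusted p-value for LPS against CON, ProNa against LPS and ProNa against CON, per the file headers. Folds were derived here from the log2 fold changes of that table. The number of libraries behind each of these tests is not given in the sources used here. KEGG pathway names per gene were taken from the same table.

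A fit with limma to values per library had been fixed before the data were examined. It could not be run without assigned libraries, and the authors' adjusted p-values with a threshold of 0.05 took its place. No SD, n or standard error accompanies them for that reason, nor can the number of samples that show a direction be given. The authors' adjusted p-values equal a Benjamini-Hochberg adjustment of their p-values over 17795, 12732 and 18540 genes in the 3 comparisons. Genes listed at exactly 1 lie outside that adjustment for a reason not given in the sources used here and were treated as having no adjusted p. The authors' own significance mark corresponds to an adjusted p under 0.05 with at least a 2-fold change, with 0 genes that differed. An adjusted p listed as 0 is one too small for the table.

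FPKM were summed over the transcripts of a gene. For 81 symbols listed with more than 1 identifier, the identifier with the highest mean FPKM was used. Depth per sample is unknown, since no counts were used. FPKM is a relative measure, so a few abundant transcripts that rise lower the values of all others. The 10 highest genes held 14.6%, 16.0% and 15.7% of the summed FPKM in CON, LPS and ProNa. The fold changes of the authors' deposited table and the log2 ratios of group mean FPKM plus 0.5 correlated across genes with Pearson's r of 0.934, 0.933 and 0.937 in the 3 comparisons, and genes are not independent replicates. Coordinates are not printed, because the annotation at hand is of another build. Strand handling is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

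Gene lists, 30 with 848 entries, were fixed before the data were examined. A signed z was derived from each deposited p-value, and cameraPR of limma 3.58.1 in R 4.3.3 compared the ranks of z in a list with those of all other adjusted genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 measured genes (28 for LPS against CON). An estimated correlation and the fry test need values per library and could not be run, so correlations of 0.05 and 0.1 were tried in their place. Where the text gives list counts with no count adjusted over the list alone, the 2 were equal. The median of each tested list was also placed among those of 10000 random lists matched on mean FPKM. For lists that passed, the text gives the percentile where it lay inside the central 95% or on the other side of the call. It is not given for lists that did not pass, although some of these lay outside the central 95%. In ProNa against LPS, for example, alternative activation markers lay at the 99.95 percentile and lysosome genes at 0.12. Tested on simulated data for ProNa against LPS (12722 genes, 100 simulations), the list test called 99.6% of lists shifted by a z of 1 and 0.4% of unshifted lists. The simulated genes were independent of one another, so these rates need not hold for lists whose members vary together. KEGG pathways with 10 to 300 measured genes were put through the same list test but were not placed among random lists.

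Shared LPS samples were simulated 100 times. The variance of a group mean was taken as equal in the 3 groups and derived from the fold changes and p-values of the authors' deposited table. This step was tested on simulated data over 12732 genes for LPS against CON and ProNa against LPS. With 200 genes moved back by a log2 change of 1, it recovered 81.5% of them. On average 4.5 other genes were called with opposite signs.

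Named genes follow a rule fixed before the data were examined: the 10 genes with the largest rise and the 10 with the largest fall in the first 2 comparisons and 5 each in the third, with an adjusted p under 0.05, at least 5 FPKM in the higher group and a gene symbol; a panel of 12 inflammatory genes; and up to 4 members per list with the smallest adjusted p. The part of the rule that asked for groups without overlapping libraries could not be applied. Members named a second time in another comparison keep their values from the same tables. Alternatives that could be run were no filter, a mean FPKM of at least 5 and a fold threshold, planned before, and further scalings, filters and list settings added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.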

Results

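RNA sequencing was carried out on RAW264.7 cells, a mouse macrophage line established from a tumour induced by Abelson murine leukaemia virus. The 9 samples fall into 3 groups of 3 by their titles: CON, LPS and ProNa. LPS is bacterial lipopolysaccharide, which macrophages sense through Toll-like receptor 4. The abbreviation ProNa is not expanded in the labels. The treatment text is identical for the samples of every group. It describes a 24 h culture in which ProNa at 1 mM was present or absent, followed by 12 h of LPS at 100 ng/mL, so the ProNa group is read here as cells given ProNa before LPS, although no label states this per sample. The values used were the authors' mean FPKM per group and the authors' table of 3 comparisons. The sources used here give neither read totals nor values assigned to single samples, so the depth is unknown and no SD could be computed. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

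The first comparison was of LPS with CON. By the group titles CON is read here as cells given neither agent and LPS as cells given LPS without ProNa. No label states this per sample. On that reading the comparison shows the response of the macrophages to LPS alone. Genes of inflammatory signalling were far higher in LPS. Tnf (ENSMUSG00000024401), which encodes a central inflammatory cytokine, stood at 36.6 FPKM in CON and 324 FPKM in LPS and was 10.6-fold higher in the authors' deposited table, with an adjusted p listed as 0. The mean FPKM of Il6 (ENSMUSG00000025746) went from 0.01 to 58.7, with an adjusted p of 2.1e-22 in the authors' deposited table. For Il1b (ENSMUSG00000027398) the means were 0.113 and 225 FPKM, with an adjusted p of 2.9e-87 in the authors' deposited table. Of the 21 measured inflammatory cytokines, 18 rose and 1 fell by the adjusted p of the authors' deposited table, and the median log2 fold change was 5.00. With 4 members listed at 0 FPKM in 1 group left out, that median was 4.63. The list test gave an adjusted p of 3.3e-06. Il1rn, which encodes the antagonist of the interleukin 1 receptor, was also among the most changed, from 42.9 to 1544 FPKM. Osm had a log2 fold change of 5.00 and an adjusted p of 7.5e-204 in the authors' deposited table. Il10, an anti-inflammatory cytokine, stayed low at 0.0333 FPKM in CON and 0.68 FPKM in LPS, with an adjusted p of 6.7e-04 in the authors' deposited table. Among 16 measured chemokines 10 rose and 1 fell by the authors' deposited table (list test, adjusted p = 8.1e-04). Cxcl2 went from 5.21 to 3914 FPKM, Ccl3 from 323 to 6767 FPKM, Ccl4 from 117 to 3015 FPKM and Ccl2 from 0.953 to 1059 FPKM. Cxcl10, which interferon induces, was 8.59-fold higher in the authors' deposited table, with an adjusted p of 1.0e-32.

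Members and feedback regulators of the NF-kB pathway mostly rose. In the list of NF-kB members and feedback regulators, 24 of 30 genes rose and 5 fell by the authors' deposited table, with a median log2 fold change of 1.56 (list test, adjusted p = 3.3e-06). Dusp1, Socs3, Tnfaip3 and Nfkbiz led the list. Socs3, a feedback inhibitor of cytokine receptors, went from 1.03 to 78.7 FPKM, and Tnfaip3, which encodes the deubiquitinating enzyme A20, from 5.74 to 58.6 FPKM. Of 31 classical activation effectors 27 rose and 2 fell by the authors' deposited table (list test, adjusted p = 1.9e-08). Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, had means of 0.08 FPKM in CON and 88.5 FPKM in LPS, with an adjusted p of 2.6e-157 in the authors' deposited table. Ptgs2, the inducible cyclooxygenase, went from 1.16 to 1125 FPKM. Acod1, which makes itaconate, went from 2.73 to 954 FPKM and Cd40 from 3.12 to 174 FPKM. Interferon-stimulated genes rose as a group: 52 of 62 rose and 0 fell by the authors' deposited table, with a median log2 fold change of 1.36 (list test, adjusted p = 1.6e-13). On the FPKM scale 47 of them rose and 5 fell. Rsad2, Cmpk2, Oasl1 and Slfn4 led this list. Rsad2, which encodes the antiviral protein viperin, went from 3.57 to 721 FPKM. Immediate early genes rose in 17 of 22 cases and fell in 3 by the authors' deposited table (list test, adjusted p = 1.5e-04), with Dusp5, Ier3, Fosl1 and Atf3 among the members with the smallest adjusted p. Arg1, an alternative activation marker, was near the floor at 0.337 FPKM in CON and 0.03 FPKM in LPS, and its adjusted p of 0.277 in the authors' deposited table did not pass.

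**Figure D1:**
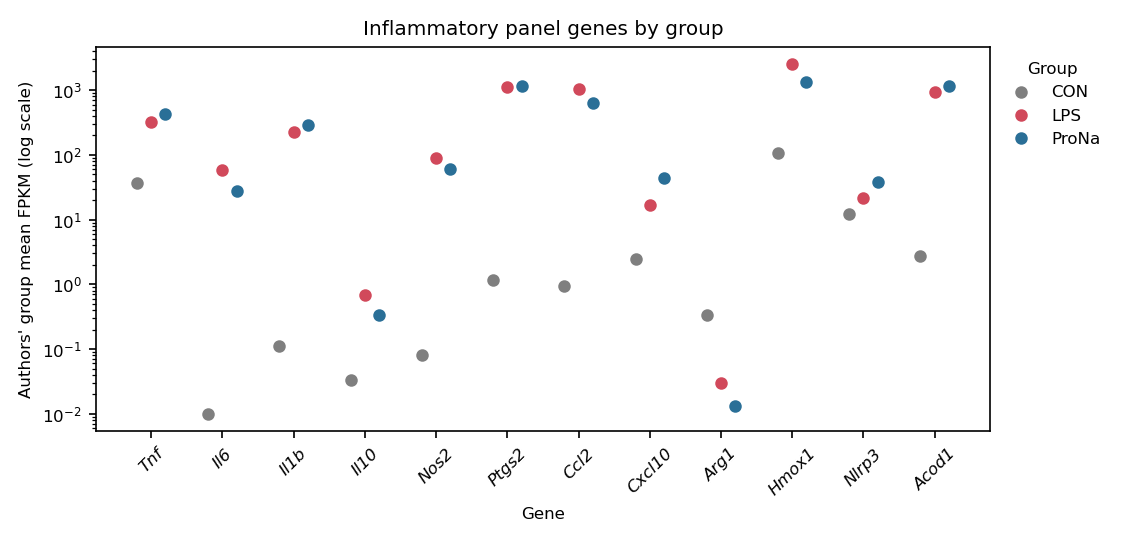
Authors' group mean FPKM (vertical axis, log scale) of 12 inflammatory panel genes (horizontal axis) in CON, LPS and ProNa, with 1 point per group mean and no error bar because values per sample were not used. Il6 stands at 0.01, 58.7 and 28.0 FPKM in the 3 groups and Cxcl10 at 2.47, 16.9 and 43.8 FPKM.

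Stress response genes also rose with LPS. In the list of the unfolded protein and integrated stress response, 30 of 33 genes rose and 1 fell by the authors' deposited table, with a median log2 fold change of 2.02 (list test, adjusted p = 2.3e-11). Ddit3 (ENSMUSG00000025408), which encodes the transcription factor CHOP, went from 17.7 to 503 FPKM, Dnajb9 from 6.60 to 130 FPKM and Trib3 from 5.97 to 94.0 FPKM. Of 35 NRF2 and antioxidant genes 24 rose and 5 fell by the authors' deposited table, or 24 and 6 adjusted over the list alone (list test, adjusted p = 1.7e-05). Hmox1, the haem-degrading enzyme, was 27.7-fold higher in the authors' deposited table, at 109 FPKM in CON and 2495 FPKM in LPS. Srxn1, Slc7a11 and Sqstm1 were the other leading members, and Sqstm1, an autophagy receptor, reached 5174 FPKM. Nlrp3, the sensor of the NLRP3 inflammasome, was 2.14-fold higher in the authors' deposited table, with an adjusted p of 5.3e-43. The inflammasome and pyroptosis list had 14 genes that rose and 6 that fell of 23 by the authors' deposited table, with an adjusted p of 0.014 in the list test and of 0.175 with a correlation of 0.1. Mlkl, Casp4 and Ninj1 led that list beside Il1b.

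Genes of proliferation and lipid synthesis fell. Of 48 cell cycle genes 47 fell and 1 rose by the authors' deposited table, with a median log2 fold change of -3.56 (list test, adjusted p = 4.1e-19). Top2a (ENSMUSG00000020914), a topoisomerase of dividing cells, went from 82.4 to 0.733 FPKM, Mki67 (ENSMUSG00000031004) from 46.8 to 0.68 FPKM, Mcm6 from 54.9 to 1.22 FPKM and Rrm1 from 53.6 to 4.55 FPKM. Among 25 cholesterol synthesis genes 22 fell and 2 rose by the authors' deposited table, with a median log2 fold change of -1.65 (list test, adjusted p = 7.6e-09). Idi1, Acat2 and Stard4 were among the leading members, and Idi1, an isomerase of the mevalonate pathway, went from 82.4 to 9.60 FPKM. LXR targets and cholesterol efflux genes fell in 12 of 19 cases and rose in 4 by the authors' deposited table, or 13 and 4 adjusted over the list alone, with an adjusted p of 0.0048 in the list test and of 0.0888 with a correlation of 0.1. Scd1, Abcg1, Lpl and Scd2 led, and Abcg1, a cholesterol exporter, went from 76.1 to 4.90 FPKM.

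Mitochondrial and ribosomal transcripts were lower in LPS. Of 26 TCA cycle genes 19 fell and 2 rose by the authors' deposited table (list test, adjusted p = 2.3e-05), and Mdh1 went from 106 to 13.4 FPKM and Idh1 from 188 to 56.0 FPKM. Nuclear genes of the respiratory chain fell in 26 of 40 cases and rose in 3 by the authors' deposited table, with an adjusted p of 6.6e-05 in the list test and of 0.0501 with a correlation of 0.1. Atp5a1 and Atp5c1 led that list. Mitochondrially encoded transcripts fell in 10 of 15 cases and rose in 2 by the authors' deposited table, with an adjusted p of 0.0027 in the list test and of 0.0516 with a correlation of 0.1. They held 7.9% of the summed FPKM in CON, 3.6% in LPS and 3.7% in ProNa. Within this list mt-Cytb went from 4455 to 1539 FPKM, whereas mt-Rnr1, a mitochondrial ribosomal RNA, went from 164 to 859 FPKM. Cytosolic ribosomal protein genes fell in 32 of 47 cases and rose in 2 by the authors' deposited table, with a median log2 fold change of -0.31 (list test, adjusted p = 1.9e-05, and 0.0989 with log2 fold changes ranked), and Rpl3 led. The propionyl-CoA and short-chain fatty acid genes fell in 15 of 28 cases and rose in 5 by the authors' deposited table, or 15 and 6 adjusted over the list alone, with an adjusted p of 0.0204 in the list test and of 0.22 with a correlation of 0.1, and on the FPKM scale 18 fell and 3 rose. Among the leading members Suclg2 went from 27.7 to 5.09 FPKM and Mmab from 15.6 to 3.42 FPKM. Hcar2, a receptor for niacin and ketone bodies, went the other way, from 7.05 to 82.8 FPKM, as did Pcca, from 12.4 to 39.3 FPKM.

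Other lists showed no common direction or lost it. Macrophage identity genes rose in 8 and fell in 13 of 23 cases by the authors' deposited table (list test, adjusted p = 0.25), and Cx3cr1 went from 184 to 0.71 FPKM, Csf1r from 888 to 27.7 FPKM and Lyz2 (ENSMUSG00000069516) from 9719 to 661 FPKM, while Ccr1 went from 1.11 to 30.1 FPKM. Lysosome genes rose in 22 and fell in 9 of 35 cases by the authors' deposited table, with an adjusted p of 0.0114 in the list test and of 0.212 with a correlation of 0.1, and on the FPKM scale 15 rose and 12 fell. Their median lay at the 53.04 percentile of random lists matched on mean FPKM. The lists of alternative activation markers, Toll-like receptor signalling, glycolysis and hypoxia response, histone deacetylases and sirtuins, antigen presentation, and p53 targets and apoptosis did not pass in this comparison, with adjusted p from 0.253 to 0.767. On the FPKM scale the medians of the antigen presentation, alternative activation and glycolysis lists turned negative, and the antigen presentation list had 8 higher and 10 lower in place of 11 and 5. Among the alternative activation markers Cd36 went from 20.7 to 176 FPKM and Trem2 from 659 to 66.9 FPKM. Many markers of other cell types had no adjusted p. Only 4 of 15 epithelial, 11 of 15 fibroblast and smooth muscle, 2 of 15 lymphocyte, 7 of 13 neutrophil and erythroid and 6 of 9 endothelial markers had one in the authors' deposited table, and none of the 3 of these lists with 5 or more measured genes passed the list test. Single members moved strongly: S100a8 went from 0.46 to 191 FPKM, Acta2 from 0.947 to 13.7 FPKM, Car2 from 10.9 to 57.1 FPKM and Ighm from 222 to 1.26 FPKM.

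By the adjusted p of the authors' deposited table, 9850 of 17795 genes changed, 5005 higher and 4845 lower in LPS, and 4956 of them by at least 2-fold. The largest rises were of Csf3, Lcn2, Edn1, Sstr5, Ccl7, Pdpn, Lif, Bcl2a1a, Il6 and Cstdc4, and the largest falls of Sema4g, Asb10, Hpgd, Nrm, Cd101, Cenpf, Pbk, Lrr1, Ankle1 and Depdc1a. Each of these genes was near or at the floor in 1 group, so their means are given in place of a fold: Csf3, which encodes granulocyte colony-stimulating factor, had 0.0167 and 859 FPKM, Lcn2 0.08 and 2004 FPKM, and Sema4g 40.1 and 0.0166 FPKM in CON and LPS. Edn1 had 40.0 FPKM in LPS and was listed at 0 in CON, and Asb10 had 14.8 FPKM in CON and was listed at 0 in LPS. The fold changes of the authors' deposited table lay above the log2 ratio of the group mean FPKM by a median of 0.24 in this comparison, 0.13 in ProNa against LPS and 0.37 in ProNa against CON. With that median subtracted from every log2 fold change (the FPKM scale), 3887 genes were higher and 6231 lower in LPS, a higher share of 38.4% in place of 50.8%.

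The second comparison was of ProNa with LPS, which shows how the groups differed in cells that the protocol text describes as LPS-treated. By this reading no group had ProNa without LPS. A change in the response to LPS therefore cannot be told apart from an effect that ProNa has without LPS. Interferon-stimulated genes were higher in ProNa. All 61 measured members rose by the authors' deposited table, with a median log2 fold change of 1.04 (list test, adjusted p = 7.8e-24, and 1.3e-05 with a correlation of 0.1). Ifit2 (ENSMUSG00000045932), an interferon-induced antiviral gene, had 68.8 FPKM in LPS and 213 FPKM in ProNa, Ifi204 53.05 and 146 FPKM, and Cmpk2 308 and 677 FPKM. Antigen presentation genes rose in 21 of 24 cases and fell in 0 by the authors' deposited table, with a median log2 fold change of 0.65 (list test, adjusted p = 1.4e-08). Tap1, a peptide transporter, had 50.2 and 97.01 FPKM, and H2-D1, a class I histocompatibility gene, 813 and 1262 FPKM. Tapbp and Psmb10 were the other leading members. On the FPKM scale 59 of the interferon-stimulated and 20 of the antigen presentation genes still rose, and 14 cholesterol synthesis genes rose and 2 fell, 6 LXR targets rose and 2 fell, 7 inflammasome genes rose and 4 fell and 3 mitochondrially encoded transcripts rose and 1 fell.

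The stress response moved the other way. In the list of the unfolded protein and integrated stress response 25 of 32 genes fell and 1 rose by the authors' deposited table, or 27 and 1 adjusted over the list alone, with a median log2 fold change of -0.42 (list test, adjusted p = 3.4e-10). Herpud1 (ENSMUSG00000031770), a component of endoplasmic reticulum-associated degradation, had 219 FPKM in LPS and 91.8 FPKM in ProNa, Ddit3 503 and 247 FPKM, Dnajb9 130 and 61.0 FPKM, and Hspa5, the endoplasmic reticulum chaperone BiP, 3073 and 1720 FPKM. Cholesterol synthesis genes rose in 18 of 25 cases and fell in 0 by the authors' deposited table, or 18 and 1 adjusted over the list alone, with a median log2 fold change of 0.52 (list test, adjusted p = 2.5e-06). Idi1 had 9.60 and 18.6 FPKM. Msmo1 and Cyp51 were also among the leading members. Nuclear genes of the respiratory chain rose in 17 of 40 cases and fell in 0 by the authors' deposited table, with a median log2 fold change of 0.19 (list test, adjusted p = 6.4e-07). On the FPKM scale 5 of these 40 rose. Their median lay at the 95.2 percentile of random lists matched on mean FPKM, inside the central 95%, so by that limit the list did not stand out from genes of similar level.

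Cytokine and chemokine genes went both ways. Of 20 inflammatory cytokines 9 were higher and 4 lower in ProNa by the authors' deposited table (list test, adjusted p = 0.276), and of 14 chemokines 5 were higher and 6 lower, or 6 and 6 adjusted over the list alone (list test, adjusted p = 0.89). The chemokine median of 0.08 became -0.05 on the FPKM scale, with 4 higher and 6 lower. Il6 was 1.94-fold lower in the authors' deposited table, with an adjusted p of 7.1e-20 and means of 58.7 and 28.0 FPKM. Tnf was 1.43-fold higher in the authors' deposited table, with an adjusted p of 1.3e-10. Il27 had 15.0 and 40.3 FPKM, Il18 17.7 and 37.7 FPKM and Tnfsf15 3.42 and 10.1 FPKM, and all 3 were higher by the authors' deposited table. Cxcl10 was 2.77-fold higher in the authors' deposited table, with an adjusted p of 1.4e-26, and Ccl9 had 710 and 1369 FPKM. Cxcl3 (ENSMUSG00000029379), a neutrophil-attracting chemokine, was 6.62-fold lower in the authors' deposited table, with an adjusted p of 5.0e-43. Ccl2 was 1.55-fold lower in the authors' deposited table, with an adjusted p of 6.1e-08, and Cxcl2 had 3914 and 2470 FPKM. Nos2 was 1.32-fold lower in the authors' deposited table, with an adjusted p of 1.3e-07. Hmox1 was 1.69-fold lower in the authors' deposited table, with an adjusted p of 2.7e-24. Nlrp3 was 1.98-fold higher in the authors' deposited table, with an adjusted p of 1.1e-39, and Acod1 1.31-fold higher, with an adjusted p of 2.4e-08. Il1b, with means of 225 and 293 FPKM, did not pass at an adjusted p of 0.141 in the authors' deposited table. Ptgs2 did not pass at an adjusted p of 0.17 in the authors' deposited table, nor Il10 at 0.386. Arg1, at 0.03 and 0.0133 FPKM, was outside the adjustment.

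**Figure D2:**
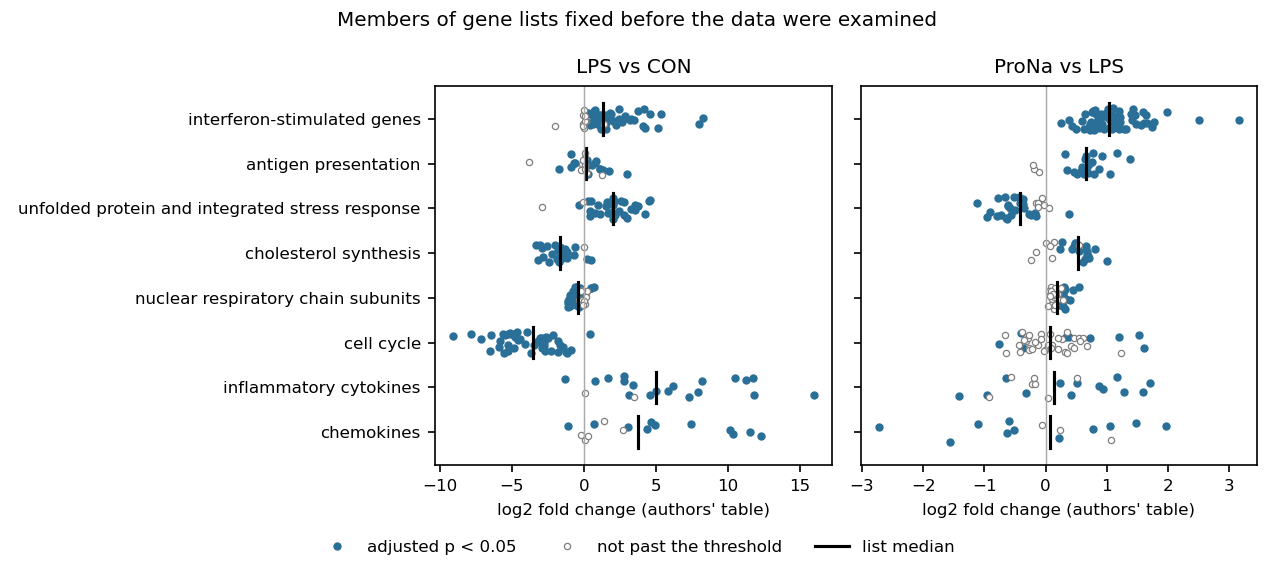
log2 fold change of each measured member of 8 gene lists (horizontal axes, from the authors' deposited table) in LPS against CON (left) and ProNa against LPS (right); filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. All 61 interferon-stimulated genes lie to the right of 0 in ProNa against LPS, and the unfolded protein and integrated stress response list has a median of 2.02 on the left and of -0.42 on the right.

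Further lists shifted, with calls that were lost at a higher correlation. Macrophage identity genes rose in 14 of 22 cases and fell in 4 by the authors' deposited table, or 14 and 5 adjusted over the list alone, with an adjusted p of 0.0065 in the list test and of 0.136 with a correlation of 0.1. Lyz2, which encodes lysozyme, had 661 FPKM in LPS and 1586 FPKM in ProNa, Fcgr1 41.7 and 106 FPKM, Itgb2 118 and 229 FPKM, and Csf1r 27.7 and 53.1 FPKM. LXR targets and cholesterol efflux genes rose in 8 of 17 cases and fell in 0 by the authors' deposited table, with an adjusted p of 0.0068 in the list test and of 0.136 with a correlation of 0.1; Lpl, the lipoprotein lipase, had 29.8 and 84.7 FPKM. The inflammasome and pyroptosis list rose in 8 of 21 cases and fell in 2 by the authors' deposited table, or 10 and 2 adjusted over the list alone, with an adjusted p of 0.0065 in the list test and of 0.136 with a correlation of 0.1. Casp1 had 169 and 228 FPKM and Gsdmd, the pore-forming gasdermin, 51.5 and 83.4 FPKM. NF-kB members and feedback regulators rose in 15 of 30 cases and fell in 5 by the authors' deposited table, or 15 and 6 adjusted over the list alone, with an adjusted p of 0.0224 in the list test and of 0.2865 with a correlation of 0.1. Tnip3 and Nfkb1 were higher and Tnfaip3 and Gadd45b lower by the authors' deposited table. Classical activation effectors rose in 17 of 30 cases and fell in 7 by the authors' deposited table, or 17 and 8 adjusted over the list alone, with an adjusted p of 0.0399 in the list test and of 0.3425 with a correlation of 0.1. Cybb and Ncf1, which encode parts of the phagocyte NADPH oxidase, had 89.0 and 204 FPKM and 58.7 and 117 FPKM, while Lcn2 had 2004 and 880 FPKM.

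The TCA cycle list rose in 13 of 26 cases and fell in 1 by the authors' deposited table, or 14 and 1 adjusted over the list alone, with an adjusted p of 0.0015 in the list test and of 0.129 with a correlation of 0.1, and on the FPKM scale 1 rose and 3 fell. Me2 led. The median lay at the 96.2 percentile of matched random lists. Mitochondrially encoded transcripts rose in 8 of 15 cases and fell in 1 by the authors' deposited table, with an adjusted p of 0.0112 in the list test and of 0.136 with a correlation of 0.1. For glycolysis and hypoxia response genes 10 of 31 rose and 4 fell by the authors' deposited table, or 11 and 4 adjusted over the list alone, with an adjusted p of 0.0441 in the list test and of 0.348 with a correlation of 0.1, and on the FPKM scale 4 rose and 7 fell. The medians of the mitochondrially encoded and the glycolysis lists lay at the 70.7 and 94.45 percentiles, so none of these 3 lay outside the central 95%. Cytosolic ribosomal protein genes had an adjusted p of 0.0065 in the list test and of 0.257 with a correlation of 0.1, with 3 of 47 higher and 1 lower by the authors' deposited table, or 2 and 1 adjusted over the list alone, and their median of 0.0782 became -0.0487 on the FPKM scale, with 0 higher and 2 lower. That median lay at the 1.56 percentile of matched random lists, low for genes of this level although the list test called the list higher. Most cell cycle genes did not pass: 6 of 45 rose and 3 fell by the authors' deposited table, or 5 and 3 adjusted over the list alone (list test, adjusted p = 0.612), and on the FPKM scale 5 rose and 8 fell. Ccnd1 (ENSMUSG00000070348), the cyclin of the G1 phase, had 52.9 FPKM in LPS and 148 FPKM in ProNa, with an adjusted p of 1.7e-110 in the authors' deposited table. Mcm6 was 2.87-fold higher in the authors' deposited table, with an adjusted p of 2.3e-10, but stayed low at 1.22 and 2.66 FPKM. Pcna was higher and Cdt1 lower, with adjusted p of 5.9e-06 and 1.3e-05 in the authors' deposited table. The propionyl-CoA and short-chain fatty acid genes had 2 of 25 higher and 1 lower by the authors' deposited table, or 2 and 0 adjusted over the list alone (list test, adjusted p = 0.487), and on the FPKM scale 1 rose and 5 fell. Acss2, an acetyl-CoA synthetase, had 11.5 and 28.1 FPKM. Histone deacetylases and sirtuins had 4 of 20 higher and 3 lower by the authors' deposited table (list test, adjusted p = 0.603), or 2 higher and 6 lower on the FPKM scale, and Hdac1 had 40.5 and 59.0 FPKM. The lists of alternative activation markers, Toll-like receptor signalling, NRF2 and antioxidant genes, lysosome, immediate early genes, and p53 targets and apoptosis did not pass, with adjusted p from 0.0718 to 0.794, and the median of the Toll-like receptor list turned negative on the FPKM scale. Markers of other cell types had at most 3 measured members per list.

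By the adjusted p of the authors' deposited table, 3901 of 12732 genes changed, 2101 higher and 1800 lower in ProNa, and 414 of them by at least 2-fold, 305 higher and 109 lower. On the FPKM scale 1376 were higher and 3213 lower, a higher share of 30% in place of 53.9%. The largest rises were of Ms4a4c, Nes, Mx1, Ifit1bl1, Rgs16, Rgcc, Ifi205, Phf11a, Fpr2 and Mcpt1. Ms4a4c (ENSMUSG00000024675) was 12.7-fold higher in the authors' deposited table, with an adjusted p of 1.1e-19 and means of 1.00 and 9.31 FPKM, and Nes, which encodes the intermediate filament nestin, had 0.60 and 6.36 FPKM. Mx1, an antiviral GTPase, was 8.91-fold higher in the authors' deposited table, with an adjusted p of 2.2e-49. Ifit1bl1, Ifi205 and Phf11a belong to families of similar genes, so reads may have been split among copies. The largest falls were of Cxcl3, Pgf, Efcab6, Sstr5, Slc4a8, Bcl2a1a, Il1f9, Dok7, Dnah7a and Fblim1. Sstr5, a somatostatin receptor, had 20.3 FPKM in LPS and 6.05 FPKM in ProNa. In Dnah7a 94.8% of the FPKM lay in transcripts whose deposited protein hit is retroviral. Bcl2a1a shares much of its sequence with its paralogs.

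The third comparison was of ProNa with CON, which sets the ProNa group against the control group. Most gene lists that passed in LPS against CON passed here in the same direction. How many single genes did so was not counted. Cytokines rose in 20 of 21 cases and fell in 1 by the authors' deposited table, with Tnf 15.2-fold higher. Interferon-stimulated genes rose in 61 of 62 cases and fell in 0 by the authors' deposited table, with a median log2 fold change of 2.28 (list test, adjusted p = 3.9e-21). Rsad2 had 1360 FPKM in ProNa and Oasl1 1533 FPKM. Cell cycle genes fell in 46 of 48 cases and rose in 1 by the authors' deposited table, with a median log2 fold change of -3.39 (list test, adjusted p = 4.5e-18). Cholesterol synthesis genes fell in 22 of 25 cases and rose in 3 by the authors' deposited table (list test, adjusted p = 8.3e-08), and genes of the unfolded protein and integrated stress response rose in 28 of 33 cases and fell in 1, or 29 and 1 adjusted over the list alone (list test, adjusted p = 2.1e-10). Antigen presentation genes rose in 20 of 27 cases and fell in 2 by the authors' deposited table (list test, adjusted p = 2.5e-05). Among further lists, chemokines (13 higher, 1 lower of 17), NF-kB members and feedback regulators (25 and 2 of 30), classical activation effectors (27 and 2 of 31), NRF2 and antioxidant genes (26 and 5 of 35, or 26 and 6 adjusted over the list alone) and immediate early genes (18 and 2 of 22, or 19 and 2 adjusted over the list alone) were higher by the authors' deposited table. Mitochondrially encoded transcripts (2 higher, 11 lower of 15) and cytosolic ribosomal proteins (7 and 33 of 47) were lower by the authors' deposited table, and both calls were lost with log2 fold changes ranked, at an adjusted p of 0.142 and 0.322. With a correlation of 0.1 the inflammasome and pyroptosis list was lost at an adjusted p of 0.113, as were the TCA cycle at 0.0855, the respiratory chain at 0.2325, LXR targets at 0.221 and lysosome at 0.1725. The medians of the lysosome and inflammasome lists lay at the 47.7 and 97.4 percentiles of matched random lists, inside the central 95%. Rescaled to FPKM, 0 cholesterol synthesis genes were higher and 22 lower, 25 stress response genes were higher and 4 lower, 24 NRF2 and antioxidant genes higher and 9 lower, and 0 ribosomal protein genes higher and 45 lower. Il6, Nos2 and Ccl2 remained far above CON, with adjusted p of 4.3e-19, 7.4e-147 and 9.6e-291 in the authors' deposited table. The largest rises were of Csf3, Lcn2, Edn1, Lif and Cstdc4 and the largest falls of Asb10, Cd101, Pbk, Sema4g and Nrm. Cstdc4 had 0.117 FPKM in CON and 429 FPKM in ProNa. By the adjusted p of the authors' deposited table, 10078 of 18540 genes changed, 5139 higher and 4939 lower, and on the FPKM scale 3502 were higher and 7065 lower, a higher share of 33.1% in place of 51.0%.

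The last question was how far the genes changed by LPS moved back in ProNa. Among 12732 genes with an adjusted p in both comparisons of the authors' deposited table, 9072 changed with LPS. Of these, 1932 (21.3%) moved in the opposite direction between LPS and ProNa and 1257 (13.9%) moved further in the direction of LPS. Genes that rose with LPS and were lower in ProNa numbered 1142, such as Il6, Cxcl3, Ddit3 and Hmox1, and genes that fell with LPS and were higher in ProNa numbered 790, such as Lyz2, Csf1r, Lpl and Idi1. Genes that rose and rose further numbered 918, such as Ifit2, Cmpk2, Cxcl10 and Tnf, and genes that fell and fell further numbered 339. Independent lists of these sizes would share 682, 700.5, 797 and 600.1 genes in these 4 classes. All of these counts rest on the scaling of the authors' deposited table. On the FPKM scale fewer genes were higher in both comparisons, and the 4 classes were not counted there, so their balance may differ. Of the 1932 genes, 1347 were still changed in the direction of LPS when ProNa was set against CON. A further 485 did not pass there, and 100 had changed against the direction of LPS. That comparison does not use the LPS samples, although the 1932 genes were selected with them. The median share of the LPS log2 change undone in these genes was 44.5%, a value that does use the LPS samples.

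**Figure D3:**
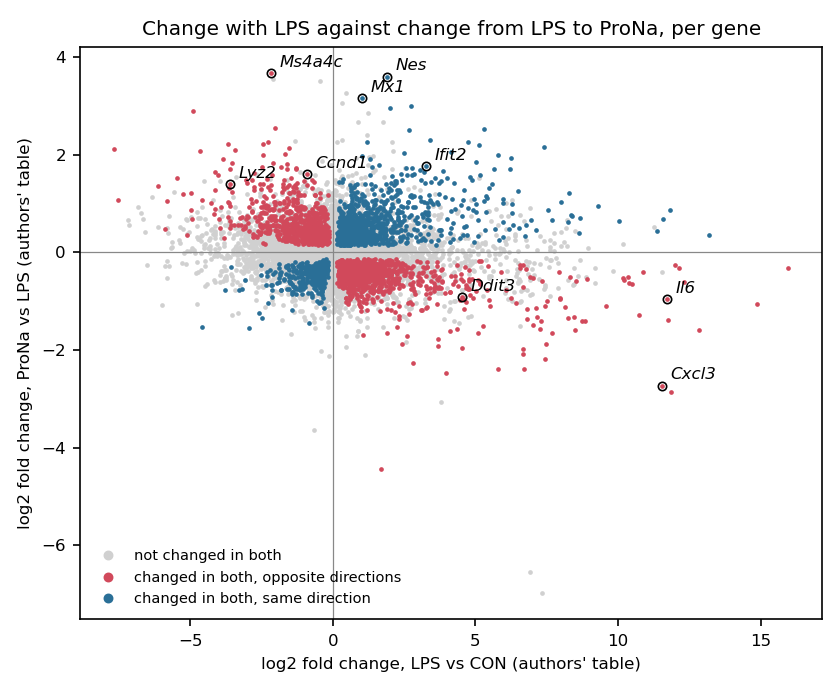
log2 fold change of ProNa against LPS (vertical axis) over that of LPS against CON (horizontal axis), both from the authors' deposited table, with 1 point per gene; red points changed in both comparisons in opposite directions (1932 genes), blue points in the same direction (1257 genes) and grey points did not change in both. Circled genes are named, with Cxcl3 and Il6 among those that rose with LPS and were lower in ProNa.

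Both comparisons share the LPS samples, which pulls the fold changes toward opposite signs without any effect of ProNa. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.111 and Pearson's r was -0.139. In 100 simulations of unchanged groups with shared LPS samples the covariance averaged -0.0487, with a lowest value of -0.0638, and r averaged -0.495. That r was fixed by the equal spread and the lack of effects in the simulation. The observed r cannot be set against it, because the LPS effects enlarge the spread by which r is divided. Only the covariance is compared here. For the 8819 genes with a mean FPKM of at least 5 the covariance was -0.0712 against a simulated -0.0136. A further 100 simulations took the LPS effects as observed, no difference between LPS and ProNa, and an equal spread in the 3 groups. They gave on average 0.03 genes called with opposite signs, at most 1, and 0.02 with the same sign. With no difference set, almost no gene can be called between ProNa and LPS. The low count was thus fixed by the setting and does not show how sharing acts where many genes are called. The LPS samples could not be split in this work, so part of the excess over chance may come from sharing them.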

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

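The tests in this part, the retroviral classes and the rule that singled out 1 locus were chosen after the values were seen. The FPKM matrix holds 1025 assembled loci that the authors' table of comparisons does not cover, and they appear here because some were above their level in CON. Of these, 32 had at least 5 FPKM in LPS and under 0.5 FPKM in CON, and 9 of the 32 had a retroviral protein hit. The opposite pattern, at least 5 FPKM in CON and under 0.5 in LPS, was shown by 14 loci. The locus MSTRG.9673, whose deposited protein hit is related to gibbon ape leukaemia virus or woolly monkey sarcoma virus, had the highest level among loci at least 10 times higher in LPS, with 1.75 FPKM in CON, 676.8 FPKM in LPS and 416.4 FPKM in ProNa. These are group means with no test and no error.

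The summed FPKM of retroviral hits of 3 other classes was lower in LPS. For transcripts with a hit related to intracisternal A particles the summed FPKM was 4360 in CON and 3403 in LPS, with 188 of 280 lower and 91 higher. For other retroviral hits the sums were 698 and 227, with 48 of 81 transcripts lower and 33 higher, so single transcripts went both ways. The largest difference was in transcripts with a protein hit related to murine leukaemia virus. Their summed FPKM was 5555 in CON, 867 in LPS and 1211 in ProNa, and of 62 such transcripts with at least 1 FPKM in a group 56 were lower in LPS than in CON. Scaling of the libraries does not account for this, because their median log2 ratio of LPS to CON lay at -1.88 relative to all genes. The FPKM summed over all retroviral hits was 1.80-fold lower in LPS. The related class of gibbon ape leukaemia virus and woolly monkey sarcoma virus gained 1171 FPKM, less than was lost. Of 89 transcripts of that class with at least 1 FPKM in a group, 63 were higher and 25 lower in LPS than in CON. The locus MSTRG.9673 with a hit of that class reached 676.8 FPKM in LPS, so the gain may rest largely on few loci. The sum over all retroviral hits includes the murine leukaemia virus class itself, and FPKM depends on transcript length. It therefore cannot decide whether reads were reassigned between proviral copies. A lower proviral output in LPS-treated cells stays open as a hypothesis, with no replicate error to weigh it by.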

How the results depend on the processing

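Alternatives other than no filter, a mean FPKM of at least 5 and the fold threshold were chosen after seeing the data, as were all alternatives run for the lists and pathways. The counts of changed genes and of genes moved back in ProNa stayed within 1.5 times their values under no filter, either FPKM minimum, median-centred fold changes, the FPKM scale and a required direction in the group means. A 2-fold threshold lowered them to 4956, 414, 5016 and, for genes moved back, 163, by its construction. On the FPKM scale the share of higher genes fell in all 3 comparisons, as given in the report, and, of the lists that passed, 2 medians changed sign: ribosomal proteins in ProNa against LPS at -0.0487 and lysosome in ProNa against CON at -0.0153. Of 50 list calls 13 were lost with log2 fold changes ranked, 6 with a mean FPKM of at least 5, 5 with z not ranked, 14 with a correlation of 0.05 and 20 with 0.1, and 0 changed direction. Calls were gained too: with z not ranked for macrophage identity (0.0078) and p53 targets and apoptosis (0.0484) in LPS against CON, for cytokines, alternative activation markers and Toll-like receptor signalling (each 0.0423) in ProNa against LPS, and for glycolysis (0.0057) and p53 targets and apoptosis (0.0127) in ProNa against CON; with a mean FPKM of at least 5 for alternative activation markers in ProNa against LPS (0.0085); and with log2 fold changes ranked for fibroblast markers in ProNa against CON (0.0441). For ProNa against LPS 14 lists passed, and 6 with a correlation of 0.05 and 5 with 0.1. With 0.1, 0 pathways passed in any comparison against 36, 103 and 62. All 175 named results kept their direction and call with no filter, as did 174 that could be placed on the FPKM scale. No paired analysis was possible because the columns used carry no replicate numbers. Pseudocounts, quantile and median-ratio rescaling, leaving out samples, other limma settings, single transcripts, an estimated correlation, fry and other splits of the samples need values per assigned library and were not run. Depth is unknown, so genes under about 0.5 FPKM carry folds that rest on few reads.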

Other observations

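The pathway tests and the tests of interferon-stimulated genes below were described after their results were seen, while the tests of shared samples and of chance overlap were written before. In the KEGG pathways of the authors' deposited table, 36 of 310 passed for LPS against CON, 23 higher and 13 lower. Protein processing in the endoplasmic reticulum was higher with 110 of 180 genes up, as was the proteasome with 40 of 54, and DNA replication was lower with 30 of 38 genes down and mismatch repair with 19 of 23. With a correlation of 0.1 none of these 4 passed, at an adjusted p of 0.889, 0.439, 0.1845 and 0.1845. For ProNa against LPS 103 of 302 pathways passed, 102 of them higher. The proteasome led with 36 of 49 genes up, a median log2 fold change of 0.27 and an adjusted p of 5.0e-09, or 0.173 with a correlation of 0.1. The Fanconi anemia pathway was the 1 that was lower, with an adjusted p of 0.0419, or 0.684 with a correlation of 0.1. Some of the higher pathways had small medians, such as salivary secretion at 0.18 and the ribosome at 0.0828. Pathways were not placed among random lists matched on mean FPKM. Whether these calls exceed a shift shared by genes of similar level therefore cannot be told.

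Interferon-stimulated genes were higher in ProNa than in LPS in all 61 measured cases. Their median log2 fold change lay 1.04 above that of all adjusted genes, which argues against a scaling of the libraries, and the upper limit of the central 95% of medians of 2000 random lists matched on mean FPKM was 0.153, which argues against expression level for this list but, as the report gives, not for every list that passed. The 28 members outside multigene families had a median of 0.93 and all 28 rose, which argues against reads shared between paralogs as the whole cause. More interferon beta transcript may lie behind the pattern, but Ifnb1 stood at 0.18 FPKM in LPS and 0.317 FPKM in ProNa with an unadjusted p of 0.482 and no adjusted p, so a difference was not detectable at these levels and earlier times were not sampled. An effect of ProNa on interferon signalling stays open as a hypothesis, found and tested on the same data.

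The genes that moved back in ProNa were set against 2 explanations. The covariance of -0.111 lay below the lowest simulated value of -0.0638. In a limit added after the result was seen, it also lay below the -0.068 that would result if all of the spread lay in the LPS samples. The spread between the shared samples, as the deposited p-values imply it, thus does not account for the whole. A shift common to all LPS samples is not part of that spread, so these values cannot exclude it. The number of genes with opposite signs was 1.40 times that of independent lists. Simulations with the observed LPS effects, shared LPS samples and no effect of ProNa called 0.03 such genes on average. That low count was fixed by the setting, since almost no gene can be called where no effect is set. The simulations assume an equal spread in the groups and do not show how sharing acts on genes that do differ between ProNa and LPS. Between them, these comparisons leave open how much of the excess is an effect of ProNa.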
